A study of Mus musculus with 32 samples.

How the data were processed

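The libraries came from mice carrying Aldh1l1-CreER, a tamoxifen-inducible recombinase driven in astrocytes, together with a Cre-dependent HA-tagged ribosomal protein Rpl22. Ribosome-bound RNA was pulled down with an anti-HA antibody from homogenised lumbar spinal cord (Trap libraries), and RNA of the same kind of homogenate before the pull-down served as Input, per the labels. Mice were uninjured or had a fracture 3, 5 or 7 weeks earlier, a model of complex regional pain syndrome, per the labels. There were 24 Trap libraries, 3 for each of the 8 combinations of sex and injury state, and 8 Input libraries, 1 for each combination. The labels do not say that every library came from a separate animal, so p-values measure the spread between these libraries.

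The authors deposited a table of RSEM estimated counts per gene for 55938 Ensembl genes and all 32 libraries, in which 6.21% to 8.53% of the values of a library were not whole. Per the submitters' processing notes, reads were checked with FastQC, trimmed with Trim Galore, aligned to GRCm38 with STAR and counted with RSEM. Tool versions and the annotation release were not given in the sources used here. RSEM divides reads shared by similar genes, so near-identical copies are uncertain. The estimated counts were rounded to whole numbers here. Library totals ranged from 17124034 to 23189228. At these totals a gene at 1 CPM rests on about 20 counts in a library, so counting error is large for genes near that level. Gene symbols were matched to 55141 identifiers by the identifier without its version, 797 had no symbol and took 0.301% of all counts, and coordinates are GRCm38 positions of GENCODE M21 genes.

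Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM normalisation, glmQLFit with robust estimation and without the legacy mode, glmQLFTest, 2-sided). P-values were adjusted by Benjamini-Hochberg over the genes tested in a comparison, and an adjusted p under 0.05 is named a call. Comparisons among Trap libraries used 1 fit of the 24 libraries with a mean per sex and injury state (15380 genes, 16 residual degrees of freedom, median biological coefficient of variation 0.146). The comparisons were each time after fracture against uninjured averaged over the sexes, within females and within males, the difference of the fracture effect between the sexes, males against females without injury, and 7 against 3 weeks. Trap was compared with Input over all 32 libraries, adjusting for sex and injury state (15913 genes). Input libraries were compared in a fit of 8 libraries with sex as an additive term, which leaves 3 residual degrees of freedom (16803 genes). CPM values are TMM-scaled, and folds are log2 ± standard error of the fit.

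Sets of genes were 41 lists of markers and pathways written before the files were seen. They were tested with camera of limma 3.58.1 (correlation preset at 0.01, log2 CPM with a prior count of 2), adjusted over the 41 lists. The same test with the correlation estimated from the data gave a p that is printed beside each call, and fry was run as another test. For counts within a list, p-values were also adjusted over the list alone. A list score is the mean log2 CPM of its genes in a library, compared within sex by an exact 2-sided permutation over 400 rearrangements. The smallest p this can give is 0.005, so adjustment over 41 lists passes only if several lists lie near it together. A carry-over index, the mean log2 CPM of neuron, oligodendrocyte, microglia and endothelial markers relative to those of astrocytes, measured RNA of these cells in the Trap libraries.

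The named genes followed a rule fixed before the data were examined, as were the groups, fits, lists and most alternatives. For Trap comparisons the rule took up to 10 called genes each way by fold (up to 5 each way within a sex, for 7 against 3 weeks, for the sex difference and for Input) with a mean of at least 1 CPM, leaving out predicted or unnamed models (symbols Gm or LOC followed by digits, ending in Rik or -ps, or clone names). It added from each list up to 4 called members with the smallest p or, where none was called, up to 2 with the smallest p as values only. It also added a fixed panel: Gfap, Aqp4, Slc1a2, Slc1a3, Aldh1l1, Glul, Gja1, Serpina3n, Lcn2, C3, Cpt1a, Ldha, Ldhb, Pkm, Hmgcs1, Apoe and Rpl22. A gene named in a comparison was followed into the others, and other genes outside the rule are said to be so where they appear. Some genes that the rule names are not reported here.

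The alternatives were DESeq2's size factors, no filter on low counts, DESeq2 1.42.0 as the test, only the groups compared, genes enriched in Trap only, the carry-over index as a covariate, the replicate number as a block, other prior counts, another list test, and leaving out each library. For Trap against Input 8 fits left out 1 library each. Added after the data were seen were a fit without 2 libraries that stood apart, a block of the replicate number within each sex, and the permutation of list scores. Other splits of the libraries into groups of equal size were refitted, 100 drawn with a fixed seed or all 10 for 3 against 3. For correlations between comparisons that share the uninjured libraries, 100 sets of unchanged groups were simulated, and the controls were also divided between the comparisons.

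The scripts' tests were checked on simulated data with 200 changed genes. For Trap at 3 weeks edgeR recovered 49.4%, 76.3% and 87.9% of genes changed 1.5-fold, 2-fold and 4-fold, with 6 false calls among 143. For Trap against Input 88.5% of all changed genes were recovered, with 7 false calls among 184. For Input at 3 weeks 74% were recovered, with 22 false calls among 170, over the 5% aimed at. The replicate block was not part of the fits reported, since the labels do not say what the number stands for.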

Results

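RNA bound to ribosomes of lumbar spinal-cord astrocytes was sequenced in 24 Trap libraries, and RNA of the whole tissue in 8 Input libraries. Each sex had 3 Trap libraries and 1 Input library per state: uninjured, or 3, 5 or 7 weeks after fracture. Total estimated counts ran from 17124034 to 23189228 in Trap and from 17981133 to 22907909 in Input. The 10 most abundant genes took 12.3% to 15.7% of the counts in Trap and 5.86% to 7.26% in Input. Mitochondrially encoded genes took under 0.5% in each Trap library, with 0.489% at most in female 3 weeks replicate 3.

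The comparison of Trap with Input asked which transcripts the pull-down enriched. Aldh1l1 (ENSMUSG00000030088.15, a folate enzyme used as the Cre driver) belongs to 25 astrocyte markers, all of which were higher in Trap, with a median log2 difference of 3.32. Aldh1l1 itself rose by 3.70 ± 0.0751, from 57.2 ± 5.13 CPM in Input (SD, n = 8) to 744 ± 73.5 CPM in Trap (SD, n = 24), and lies on chromosome 6 at 90486427 to 90600203 of GRCm38. The water channel Aqp4 rose by 3.19 ± 0.0884, the filament gene Gfap by 3.11 ± 0.0655, the connexin Gja1 by 3.40 ± 0.0631 and the lipid carrier Apoe by 3.49 ± 0.0856. Markers of microglia, oligodendrocytes and endothelial cells went the other way. All 17 microglia markers (median -3.85, Csf1r -4.03 ± 0.0796), all 18 oligodendrocyte markers (median -2.41, Mobp -3.15 ± 0.0916) and all 13 endothelial markers (median -2.82) were lower. Neuronal transcripts were depleted as well, with all 20 neuron markers lower (median -4.02, the vesicle gene Syt1 -4.44 ± 0.110). The 19 dorsal horn peptide and receptor genes were all lower (median -4.50), among them the opioid receptor Oprm1 at -5.50 ± 0.227 and the substance P gene Tac1 at -5.04 ± 0.149.

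**Figure D1:**
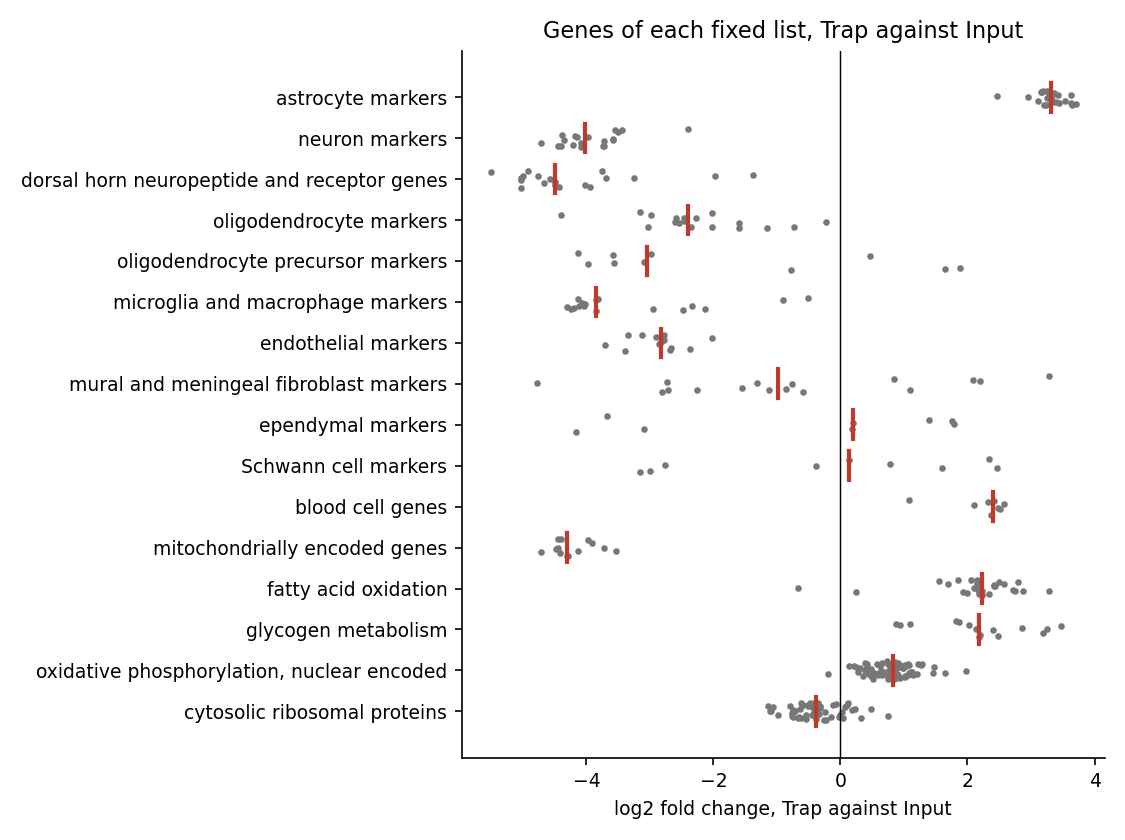
Log2 fold change of Trap against Input (x axis) for the genes of 16 lists, 1 grey point per gene, with a red bar at the median of each list. Astrocyte markers sit around a median of 3.32 and neuron markers around -4.02.

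Astrocyte metabolism, the subject of the study, was over-represented in the pulled-down RNA. All 15 glycogen genes were higher (median 2.18), led by the glycogen phosphorylase Pygm at 3.47 ± 0.0965, and 27 of 28 fatty acid oxidation genes (median 2.23), with the acyl-CoA dehydrogenase Acadm at 2.87 ± 0.0516. Of the tricarboxylic acid cycle and pyruvate genes 24 of 26 were higher (median 0.99), Idh2 by 2.90, while the pyruvate dehydrogenase kinase Pdk3 was lower, by -3.02. Glycolysis and lactate genes had 19 of 24 higher (median 1.05), lipid synthesis 20 of 24 (median 2.22), cholesterol synthesis and transport 21 of 26 (median 1.35), and nuclear oxidative phosphorylation genes 73 of 75 (median 0.82). The 13 mitochondrially encoded genes, which cytosolic ribosomes do not translate, were all lower (median -4.30, mt-Co1 -4.44 ± 0.111). Gap junction, potassium and water genes had a median of 3.02 and glutamate and GABA genes one of 2.10, with the glutamine synthetase Glul at 2.16 and the GABA carrier Slc6a11 at 3.27. All 8 blood cell genes were higher in Trap (median 2.40), such as the globin Hba-a1 at 2.37 ± 0.300, although camera did not call that list (adjusted p 0.0818). Col1a2, a collagen gene of fibroblasts, was also higher, at 3.28 ± 0.0900.

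edgeR called 13992 of 15913 genes, 7058 higher and 6934 lower, of which 3463 and 4243 differed over 2-fold. Scaling by DESeq2's size factors shifted the median of all genes by -0.10 on the log2 scale. Camera called 28 of 41 lists, 21 up and 7 down. With the estimated correlation 0 lists passed adjustment (smallest adjusted p 0.116), 10 had p under 0.05 unadjusted, and fry called 40. Among them p was 0.0140 for astrocyte markers, 0.00846 for microglia, 0.0277 for dorsal horn genes, 0.00375 for glycogen, 0.0174 for fatty acid oxidation, 0.0265 for the tricarboxylic acid cycle and 0.00765 for gap junction genes. It was 0.0939 for neuron, 0.174 for oligodendrocyte and 0.0897 for endothelial markers, 0.0940 for mitochondrially encoded genes, 0.0941 for glycolysis, 0.296 for oxidative phosphorylation, 0.0499 for lipid synthesis, 0.0504 for cholesterol and 0.0497 for glutamate genes.

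The series asks how astrocytes differ in acute and chronic pain, and the comparison at 3 weeks after fracture asked which astrocyte transcripts differed from the uninjured cord at that time. Rflnb, which encodes an actin-regulating refilin, fell by 0.75 ± 0.0947 on the log2 scale, from 33.1 ± 4.63 to 19.6 ± 2.81 CPM (SD, n = 6 each). The intracellular water channel Aqp6 fell from 22.4 ± 3.68 to 13.8 ± 4.27 CPM, at -0.73 ± 0.107, the actin-binding supervillin gene Svil from 22.4 ± 5.35 to 12.5 ± 1.83 CPM, at -0.82 ± 0.144, and the gap junction gene Gja1 from 2665 ± 120 to 2119 ± 179 CPM, at -0.33 ± 0.0645. The imprinted gene Nnat rose from 318 ± 36.1 to 452 ± 63.1 CPM, at 0.50 ± 0.0768, the matricellular gene Smoc1 from 24.6 ± 1.62 to 38.2 ± 9.71 CPM, at 0.62 ± 0.102, and the FGF receptor relative Fgfrl1 from 130 ± 23.6 to 184 ± 14.5 CPM, at 0.50 ± 0.0965. Gfap, the usual marker of reactive astrocytes, was at 0.22 ± 0.0792 and not called (adjusted p 0.347).

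edgeR called 17 of 15380 genes, 5 higher and 12 lower. The adjusted p was 0.000577 for Rflnb, 0.00389 for Aqp6, 0.00510 for Nnat, 0.00786 for Smoc1, 0.0176 for Svil, and 0.0267 for Gja1 and Fgfrl1. The other lower genes were the adhesion gene Tns3 (-0.47), Galnt18 (-0.55), Ky (-0.72), Bcam (-0.33), Amhr2 (-0.62), the low-expressed St14 (-1.94), and Mat2a (-0.64) with an identical unnamed copy that shares its reads, so both are uncertain. The other higher genes were Rassf10 (0.89) and 2900052N01Rik (0.81). St14, 2900052N01Rik and the copy of Mat2a lie outside the naming rule and were chosen after their values were seen. In GRCm38 Rflnb (ENSMUSG00000020846.6) lies on chromosome 11 at 76019194 to 76027782, Nnat (ENSMUSG00000067786.16) on chromosome 2 at 157560078 to 157562522, Smoc1 (ENSMUSG00000021136.13) on chromosome 12 at 81026808 to 81186414, and Gja1 (ENSMUSG00000050953.10) on chromosome 10 at 56377330 to 56402513. Nnat, Rflnb and Aqp6 were called whichever of the 12 libraries was left out, Smoc1 in 11 of those 12 fits, Mat2a in 9, Svil in 8, Galnt18 and Tns3 in 6, Fgfrl1, Bcam and Rassf10 in 5, Gja1 and Ky in 4, and Amhr2 in 3. With only the groups compared in the fit Fgfrl1, Amhr2, Galnt18, Tns3 and Bcam were not called. The count of calls fell to 3 without male uninjured replicate 2 and rose to 47 without female 3 weeks replicate 3 (24 higher, 23 lower), and DESeq2 called 135.

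**Figure D2:**
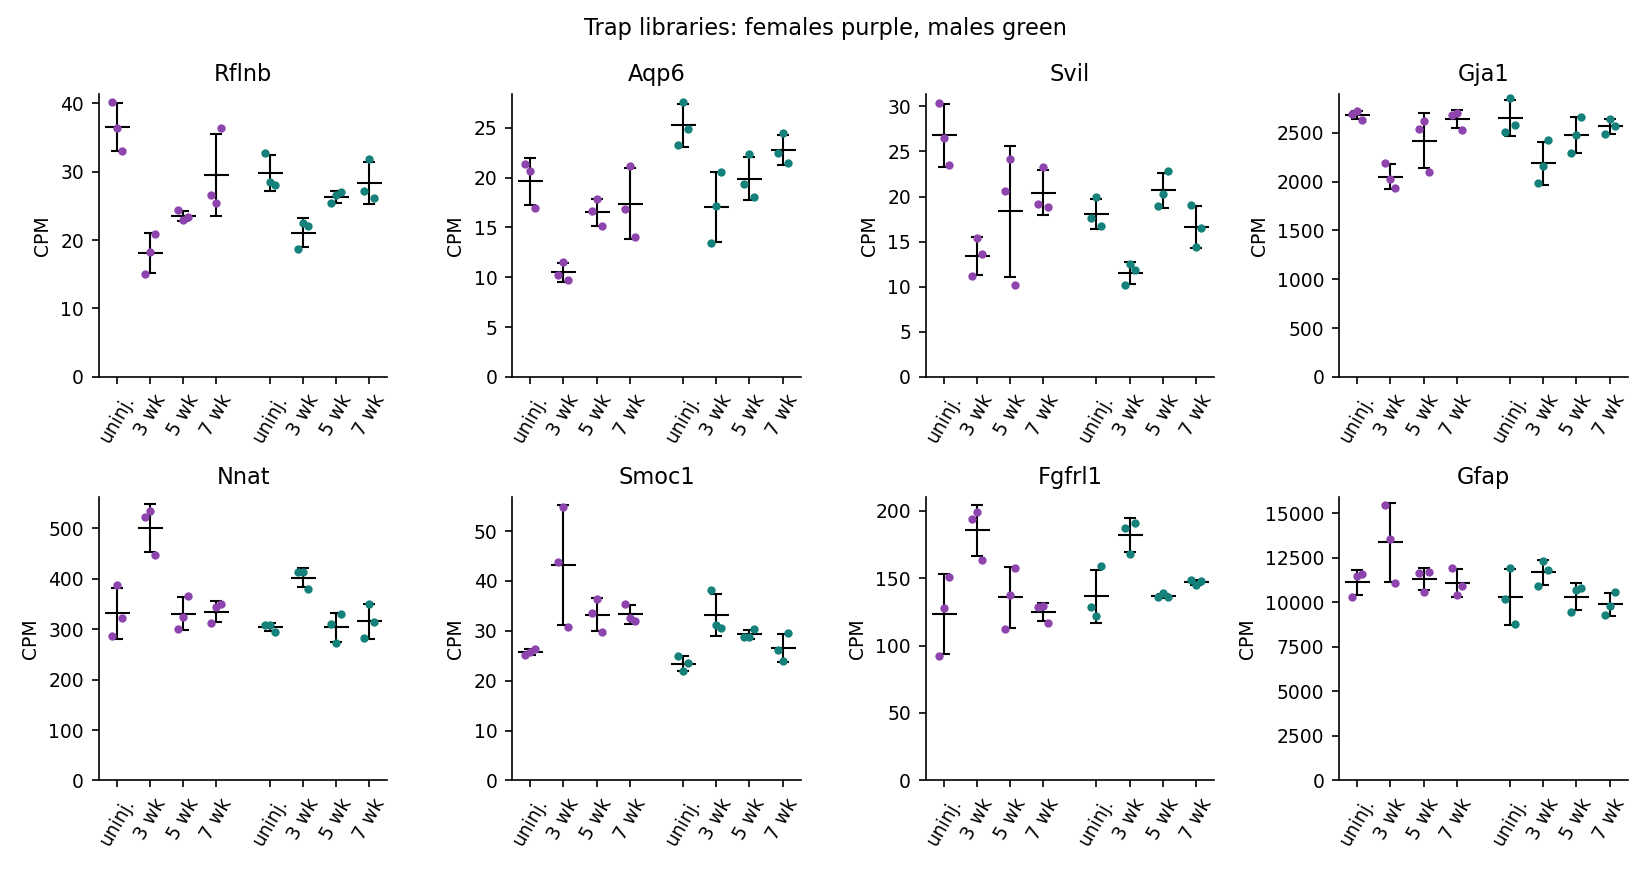
CPM (y axis) of 8 genes in each Trap library by injury state (x axis), females purple and males green, with black bars for the mean ± SD of each group (n = 3). Rflnb, Aqp6, Svil and Gja1 are lower at 3 weeks than in uninjured mice, and Nnat, Smoc1 and Fgfrl1 higher; Gfap was not called.

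All 17 genes had the same sign in both sexes, against 56.9% of all genes, but they were chosen by a call on the 2 sexes together, which favours equal signs. In Trap against Input 16 of the 17 were called higher in Trap, all but St14, against 7058 of all 15913 genes. In the whole tissue at 3 weeks 14 of the 17 had the same sign and 7 were called: Nnat (0.54), Fgfrl1 (0.64), 2900052N01Rik (0.64), Tns3 (-0.57), Gja1 (-0.29) and the Mat2a pair (-0.57). Of all 16803 genes 182 were called there. The Mat2a pair has identical values, so its members are not separate in these counts. It is not known whether Trap and Input libraries share animals, so the agreement may not be independent. At 5 and 7 weeks 16 of the 17 had the sign of 3 weeks, against 67.3% and 64.5% of all genes; the shared uninjured libraries favour equal signs. Rflnb was at -0.40 ± 0.0931 at 5 weeks and -0.19 ± 0.0923 at 7 weeks, neither called.

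Genes that answer to glucocorticoids were lower at 3 weeks by camera: 17 of 18 were negative, with a median of -0.35. With the estimated correlation p was 0.00941, which did not pass adjustment (0.386). The steroid-induced leucine zipper gene Tsc22d3 was at -0.72 ± 0.150 (adjusted p 0.0651) and the cell cycle inhibitor Cdkn1a at -0.88 ± 0.211 (adjusted p 0.109). Also called lower by camera were lists with 23 of 26 tricarboxylic acid cycle and pyruvate genes negative (median -0.09, p 0.0576), 19 of 24 glycolysis and lactate genes (median -0.11, the phosphofructokinase Pfkp -0.41, p 0.0924), 13 of 15 glycogen genes (median -0.11, Ppp1r3g -0.42, p 0.0316) and 23 of 28 fatty acid oxidation genes (median -0.06, p 0.256). All 57 cytosolic ribosomal protein genes were positive, with a median of 0.20 (p 0.145), such as Rpl22 at 0.21 ± 0.0763 (adjusted p 0.362). Of the panel, Aqp4 was at -0.03, Apoe at 0.01, Slc1a2 at -0.10, Slc1a3 at -0.13, Aldh1l1 at -0.09, Glul at -0.21, Serpina3n at 0.20, C3 at -0.18, Cpt1a at -0.10, Ldha at 0.03, Ldhb at -0.10, Pkm at -0.16 and Hmgcs1 at 0.02, none of them called by edgeR. Lcn2 was at -1.30 ± 1.78, an error larger than the difference, with 44.5 CPM in female uninjured replicate 2 and 0.0457 to 4.59 CPM in the other 23 Trap libraries. That uninjured library also had 197 CPM of Serpina3n (other uninjured libraries 89.4 to 117) and 391 CPM of C3 (others 207 to 283).

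Camera called 13 lists at 3 weeks, 1 up and 12 down, and with the estimated correlation 0 were called, 2 having p under 0.05 unadjusted. fry also called 0, with 4 lists at p under 0.05 unadjusted. Of the glucocorticoid genes edgeR called 0 of 18 over all genes against 5 lower adjusted over the list alone, and of the glycogen genes 0 over all genes against 3 lower adjusted over the list alone. The other lists called were astrocyte markers (median -0.07, p 0.328), gap junction, potassium and water genes (-0.12, p 0.141), glutamate and GABA genes (-0.08, p 0.146), the unfolded protein response (-0.12, p 0.0973), synapse and axon guidance factors (-0.11, p 0.195), autophagy (-0.05, p 0.172) and hypoxia genes (-0.09, p 0.0627). Not called were nuclear oxidative phosphorylation (median -0.01), cholesterol synthesis (0.00) and pan-reactive genes, whose median of 0.09 and mean of -0.17 differ in sign. That mean is lowered by female uninjured replicate 2, whose pan-reactive score was 5.10. The score was 3.24 to 3.65 in the other uninjured libraries and 3.41 to 4.35 at 3 weeks. Without female 3 weeks replicate 3 and male 7 weeks replicate 2, a fit chosen after the data were seen, camera called 12 lists, 6 of them among the 13. The astrocyte, gap junction, glutamate, synapse, fatty acid oxidation, autophagy and hypoxia lists were not called there, while pan-reactive (adjusted p 0.00811), interferon (0.00121) and cytokine genes (0.00965) were called up, and neuron (0.000886), oligodendrocyte (0.0266) and nuclear oxidative phosphorylation genes (0.000886) down. An exact permutation of list scores within sex called 0 of 41 lists at 3 weeks, with a smallest adjusted p of 0.137. Its p cannot fall below 0.005, so a single changed list could not pass adjustment and the 0 says little.

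**Figure D3:**
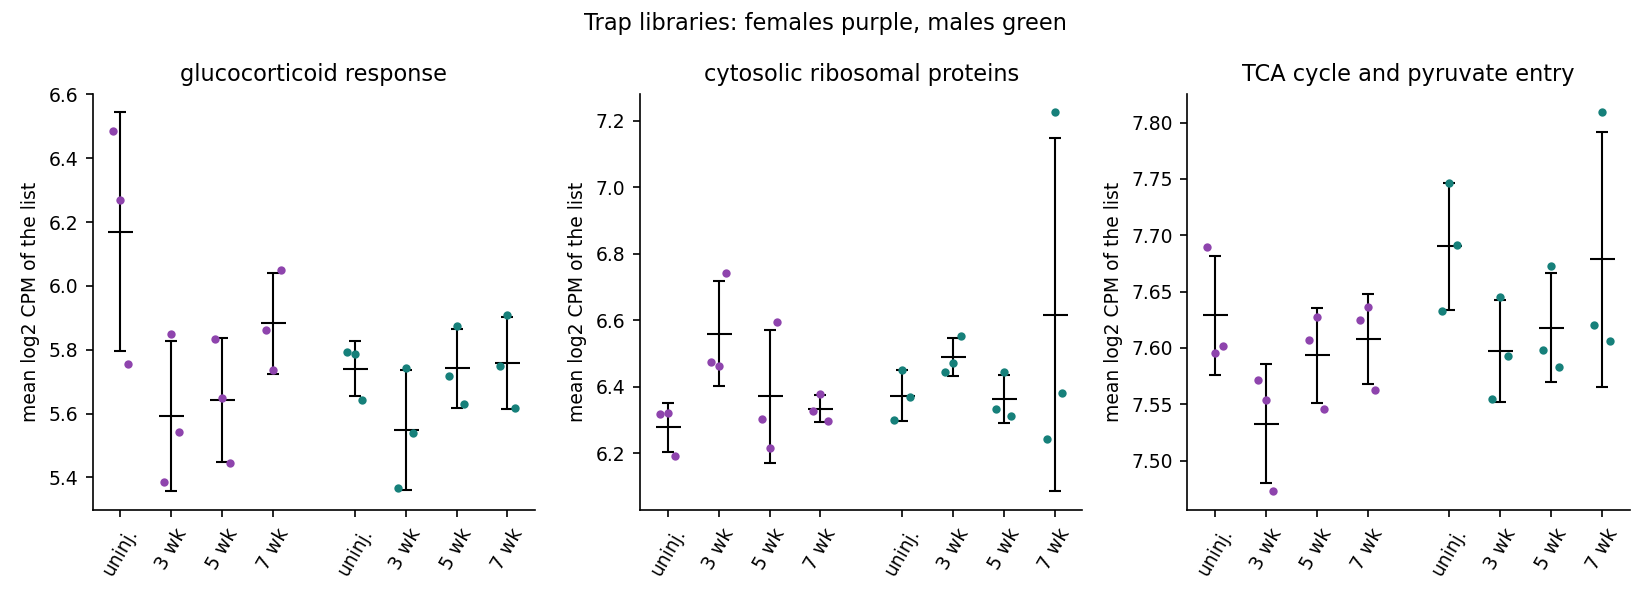
Mean log2 CPM (y axis) of glucocorticoid response, cytosolic ribosomal protein, and tricarboxylic acid cycle and pyruvate genes in each Trap library by injury state (x axis), females purple and males green, with black bars for the mean ± SD of each group (n = 3). Male 7 weeks replicate 2 stands at 7.23 for ribosomal protein genes, above the other 7 week libraries at 6.24 to 6.38.

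At 5 and 7 weeks, the later times of the pain model, edgeR called none of the named genes in the fit of both sexes. Gfap was at 0.01 ± 0.0792 and -0.03 ± 0.0792, Gja1 at -0.12 ± 0.0644 and -0.03 ± 0.0644, and Pkm at -0.09 ± 0.0578 and -0.04 ± 0.0578, at 5 and 7 weeks against n = 6 uninjured. The glucocorticoid target Zbtb16 was at -0.81 ± 0.275 and -0.60 ± 0.273. edgeR called 0 genes at 5 weeks, with 425 at an unadjusted p under 0.05, where DESeq2 called 1. At 7 weeks edgeR called 0 genes, with 438 at an unadjusted p under 0.05, where DESeq2 also called 0.

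By camera at 5 weeks all 12 measured endothelial markers were higher (median 0.50, estimated-correlation p 0.0856), as were 17 of 18 oligodendrocyte markers (0.18, p 0.302). Mural and meningeal (0.25, p 0.00966), ependymal (0.18, p 0.0226) and Schwann cell markers (0.18, p 0.0890) were also up, and microglia markers down (-0.31, p 0.0616). All 18 glucocorticoid genes were negative (median -0.16, p 0.0658), as were 22 of 24 glycolysis and lactate genes (-0.09, p 0.0692). The unfolded protein response (-0.09, p 0.0322), hypoxia genes (-0.09, p 0.0105), the tricarboxylic acid cycle (-0.06, p 0.150), astrocyte markers (-0.06, p 0.313), fatty acid oxidation (-0.04, p 0.295), gap junction genes (-0.04, p 0.235) and autophagy (-0.03, p 0.233) made up the rest of the 15 lists. With the carry-over index as a covariate the oligodendrocyte, astrocyte, Schwann cell, fatty acid oxidation, gap junction and autophagy lists were not called, and the difference in mean log2 CPM went from 0.21 ± 0.233 to 0.09 ± 0.176 for oligodendrocyte and from 0.36 ± 0.240 to 0.22 ± 0.160 for endothelial markers. The endothelial score was 1.14 in female 5 weeks replicate 3 (other 5 week libraries -0.12 to 0.45) and the Schwann cell score 4.92 in male 5 weeks replicate 3 (others 3.41 to 3.82). At 7 weeks 2 lists were called, all 57 ribosomal protein genes being positive (median 0.18, p 0.155) and 19 of 20 neuron markers (0.16, p 0.385). The ribosomal difference in mean log2 CPM went from 0.15 ± 0.124 to 0.000251 ± 0.0691 without male 7 weeks replicate 2, and neither list was called without that library and female 3 weeks replicate 3. With the estimated correlation 0 lists were called at either time, with 4 at 5 weeks and 1 at 7 weeks at p under 0.05 unadjusted, and fry called 0, with 2 and 0 at p under 0.05.

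Within females at 3 weeks Rflnb fell by 1.01 ± 0.134, from 36.5 ± 3.56 to 18.1 ± 2.93 CPM (SD, n = 3 each; adjusted p 0.00138), Aqp6 by 0.90 ± 0.157 and the glycosyltransferase gene Galnt18 by 0.83 ± 0.146 (adjusted p 0.0299 for both). Nnat rose by 0.60 ± 0.109 (adjusted p 0.0373). Anxa1 (4.22 ± 0.723) and the neutrophil gene Retnlg (3.61 ± 0.723), both low-expressed and named after their values were seen, completed the 6 calls of edgeR, 3 higher and 3 lower. Female 3 weeks replicate 2 had 2.75 CPM of Anxa1 (0.696 and 0.577 in the other 2) and 2.10 CPM of Retnlg (0.696 and 0.444), and without it 1 gene was called. The blood cell score was 4.69 to 5.02 in these 3 libraries and 3.92 to 4.58 in uninjured females. With only the groups compared in the fit 0 were called, Rflnb alone was called whichever of the 6 libraries was left out, and DESeq2 called 69. In males Rflnb was at -0.49, Aqp6 at -0.56 and Gja1 at -0.28 ± 0.0912 at 3 weeks, and edgeR called 0 genes, with 474 at an unadjusted p under 0.05 and 1 by DESeq2. edgeR called 0 genes in females at 5 and 7 weeks (595 and 377 unadjusted, 0 and 0 by DESeq2) and in males (338 and 366 unadjusted, 1 and 1 by DESeq2).

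Among the lists that camera called in females at 3 weeks, glucocorticoid genes had a median of -0.64 (estimated-correlation p 0.00638, adjusted 0.262), and 0 of 18 called over all genes by edgeR against 9 lower adjusted over the list alone; in males the median was -0.12 (p 0.153). The female difference in mean log2 CPM was -0.58, and -0.42 without female uninjured replicate 1; that library and replicate 2 had 6.48 and 6.27, the other 22 Trap libraries at most 6.05. Cholesterol genes had medians of 0.13 in females (p 0.187) and -0.16 in males, where 24 of 26 were negative (p 0.0457). The female difference in their mean log2 CPM was 0.10, and 0.03 without female 3 weeks replicate 1, and uninjured libraries had 7.27 ± 0.121 in females and 7.44 ± 0.107 in males (SD, n = 3 each). Ribosomal protein genes were up in both, at 0.29 in females (p 0.140) and 0.11 in males (p 0.423). Males had 74 of 75 nuclear oxidative phosphorylation genes slightly negative (-0.08, p 0.434) and glycolysis genes at -0.15 (p 0.0320). The male differences in mean log2 CPM went from -0.09 to -0.05 for oxidative phosphorylation and from -0.19 to -0.10 for glucocorticoid genes without male 3 weeks replicate 1, and from -0.11 to -0.07 for cholesterol genes without male uninjured replicate 2. Camera called 10 lists in each sex at 3 weeks, 8 in females and 4 in males at 5 weeks, and 6 and 3 at 7 weeks. At 5 weeks they included glucocorticoid genes in females (-0.42, p 0.0147) and oxidative phosphorylation in males (-0.12, p 0.291; difference in mean log2 CPM -0.12, and -0.08 without male uninjured replicate 2). With the estimated correlation 0 of these lists were called, with 2 in females and 3 in males at p under 0.05 unadjusted at 3 weeks, and fry called 0.

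Whether the fracture effect differed between the sexes was tested directly. By camera cholesterol genes differed at 3 weeks, by -0.30 in males minus females, and glucocorticoid genes by 0.30 at 3 weeks and 0.38 at 5 weeks. None of these passed adjustment with the estimated correlation (p 0.0129, 0.0744 and 0.0446; adjusted 0.528, 0.994 and 0.990). The mean log2 CPM of glucocorticoid genes was 5.59 and 5.55 in females and males at 3 weeks, 5.64 and 5.74 at 5 weeks, and 6.17 ± 0.374 and 5.74 ± 0.0858 in uninjured mice (SD, n = 3 each). Without female uninjured replicate 1 the sex difference of this score went from 0.39 to 0.23 at 3 weeks and from 0.53 to 0.37 at 5 weeks. edgeR called 0 single genes at 3, 5 and 7 weeks (398, 466 and 303 at an unadjusted p under 0.05), and DESeq2 called 1 at each. Camera called 4, 3 and 4 lists at these times, and the estimated correlation and fry called 0; the estimated correlation gave 1, 1 and 0 lists at p under 0.05 unadjusted.

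Uninjured males and females differed in genes of the sex chromosomes. The Y-linked Ddx3y was higher in males by 6.91 ± 0.195 (n = 3 each; adjusted p 8.16e-18), as were Uty, Kdm5d and Eif2s3y. The X-linked Eif2s3x was lower by -0.58 ± 0.0846 (adjusted p 0.00153) and Xist, the RNA that silences an X chromosome, by -6.21 ± 1.16 (adjusted p 0.0277), though Xist was called in 1 of 6 fits that left out a library. These were the 6 calls of edgeR, 4 higher and 2 lower, and DESeq2 called 11. Camera called 9 lists: cholesterol (0.22, estimated-correlation p 0.0124), pan-reactive (-0.43, p 0.0473), glucocorticoid (-0.26, p 0.0558), A1 reactive (-0.23, p 0.129), tricarboxylic acid cycle (0.08, p 0.176), mitochondrially encoded (-0.31, p 0.271), oxidative phosphorylation (0.14, p 0.293), ribosomal protein (0.10, p 0.501) and sex chromosome genes (p 0.0837). The last list had a median of -0.57, but its mean of 1.77 and the test pointed up. With the estimated correlation 0 lists were called (2 at p under 0.05 unadjusted, smallest adjusted p 0.510), and fry called 1, with 2 at p under 0.05. Female uninjured replicate 2 had a mean log2 CPM of 5.10 for pan-reactive and 3.55 for A1 reactive genes, where the other 5 uninjured libraries had 3.24 to 3.65 and 2.90 to 3.20, and without it the sex difference of these scores went from -0.62 to -0.09 and from -0.18 to -0.01. It went from -0.41 to -0.12 for mitochondrially encoded genes without male uninjured replicate 3, from 0.06 to 0.03 for the tricarboxylic acid cycle without male uninjured replicate 2, from 0.10 to 0.05 for ribosomal protein genes without female uninjured replicate 3, and from -0.43 to -0.27 for glucocorticoid genes without female uninjured replicate 1.

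The comparison of 7 with 3 weeks asked what differed between a later and an earlier time after fracture. Nnat fell by 0.47 ± 0.0768 and Rflnb rose by 0.57 ± 0.0952 (n = 6 each; adjusted p 0.0204 for both), each back toward its uninjured level. They were among 3 calls of edgeR, 1 higher and 2 lower, and DESeq2 called 57. With only the groups compared 0 were called, and so without female 3 weeks replicate 1, while 38 were called without male 7 weeks replicate 2. Camera called 12 lists, 11 up and 1 down, with glucocorticoid genes at 0.26 (estimated-correlation p 0.0275) and Schwann cell markers at 0.21 (p 0.0388), and pan-reactive genes at -0.25 (p 0.154). With the estimated correlation 0 lists were called (2 at p under 0.05 unadjusted, smallest adjusted p 0.796), and fry called 0, with 2 at p under 0.05. The Schwann cell score was 4.85 in female 7 weeks replicate 1 and 3.55 to 4.11 in the other 7 week libraries.

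The Input libraries (n = 2 per state) showed the whole tissue. At 3 weeks several neuropeptide genes rose: Vgf by 0.99 ± 0.0617 (adjusted p 1.65e-07), Penk by 0.91 ± 0.0627 (adjusted p 4.55e-07), Gal by 1.86 ± 0.157, Tac1 by 1.05 ± 0.0998 and Crh by 2.58 ± 0.304. Whole tissue does not show in which cells they rose. Sprr1a rose by 4.43 ± 0.515, from 0.162 ± 0.230 to 3.62 ± 0.905 CPM, and Atf3 by 2.29 ± 0.373, from 0.650 ± 0.130 to 3.21 ± 2.15 CPM (SD, n = 2 each). The oligodendrocyte precursor gene Gpr17 fell by 0.88 ± 0.0912, the thyroid hormone enzyme gene Dio2 by 0.92 ± 0.118, and the glucocorticoid target Tsc22d3 by 0.49. Vgf, Penk, Tac1 and Tsc22d3 lie outside the naming rule for Input and were chosen after their values were seen. edgeR called 182 of 16803 genes, 73 higher and 109 lower, and DESeq2 called 196. In 1 fit of all 32 libraries 7 were called.

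Dorsal horn genes had a median of 0.30 in Input at 3 weeks, 6 called over all genes and 9 higher adjusted over the list alone (camera, estimated-correlation p 0.0213). Microglia markers had 0.25, 1 called and 10 higher adjusted over the list alone (p 0.0570), and cholesterol genes 0.18, 4 called and 14 higher adjusted over the list alone (p 0.0834). Glucocorticoid genes had -0.56, 4 called, and 10 lower and 1 higher adjusted over the list alone (p 0.0818). At 5 weeks edgeR called 18 genes, 17 higher and 1 lower, such as Fzd10 (1.20 ± 0.211), Tmem160 (0.87 ± 0.112) and Glrx5 (0.58 ± 0.0715), and DESeq2 called 22. Nnt, listed at 0 in the uninjured and 3 week libraries, and Pagr1a had the largest differences there and are uncertain. At 7 weeks 36 were called, 32 higher and 4 lower, with Tmem160 at 1.03 ± 0.112, Coq8a at -1.25 ± 0.160 and Tns3 at -0.37 ± 0.0639, and DESeq2 called 41. In 1 fit of all 32 libraries 0 were called at both times. Camera called 16, 9 and 6 lists at 3, 5 and 7 weeks, 0 with the estimated correlation (3, 1 and 2 at p under 0.05 unadjusted) and 0 with fry. Glucocorticoid genes were down again at 5 (-0.35, p 0.157) and 7 weeks (-0.36, p 0.115).

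Across 15380 genes, which are not independent replicates, fold changes in females and males correlated at Pearson r 0.151 at 3 weeks (Spearman 0.184), 0.0394 at 5 weeks (-0.0448) and 0.0752 at 7 weeks (0.0647). The carry-over index, in log2 units, was higher after fracture by 0.0644 at 3 weeks, 0.159 at 5 weeks and 0.119 at 7 weeks (exact permutation, n = 6 each, p 0.818, 0.320 and 0.487; adjusted over 3 tests 0.818, 0.731 and 0.731), each within the spread between libraries. Its mean was -8.53 ± 0.245 in uninjured libraries and -8.46 ± 0.509 at 3 weeks.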

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

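The tests of clock genes, of 1 library at 7 weeks and of binding to beads were chosen after the results were seen, and the adjusted permutation p decides the ribosomal test in place of the unadjusted p written beforehand.

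Glucocorticoid response genes were lower in Trap at 3 weeks, with a mean log2 CPM difference of -0.38 ± 0.119 (-0.58 in females, -0.19 in males), which an exact permutation within sex did not pass after adjustment (p 0.03, adjusted 0.239). The permutation p cannot fall below 0.005, so this list could hardly pass adjustment. The carry-over index argues against RNA of neurons, oligodendrocytes, microglia and endothelial cells as the whole cause. It differed by only 0.0644 at 3 weeks, and with it as a covariate the list difference was -0.37 ± 0.118. RNA of blood, Schwann, mural and ependymal cells lies outside the index and was not tested. The list was also lower in Input at 3 weeks. Dependence on 1 library stays open: the difference ran from -0.48 to -0.30 as each library was left out, with a jackknife error of 0.165. The time of day of tissue collection is a candidate explanation that also stays open, since clock genes of opposite phase moved apart at 3 weeks by 0.33 ± 0.155 in Trap (exact permutation p 0.135) and by 0.52 ± 0.121 in Input, and over the 24 Trap libraries the clock difference and the list score had Pearson r -0.410 (permutation p 0.0476, adjusted over 2 relations 0.0952; Spearman -0.282, p 0.178; r -0.375 without the 2 farthest libraries) but -0.246 (p 0.245) within groups. A lower stress hormone tone after fracture, the biological reading that the design allows, is equally open and was not tested.

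Cytosolic ribosomal protein genes were higher in Trap at 3 weeks by 0.20 ± 0.124 in mean log2 CPM. Genes matched on exonic length and expression had a mean median of 0.0205 (SD 0.0112) against 0.20 for the list. That met the bound written beforehand for excluding a bias by exonic length. The length of the transcripts themselves was not measured, so a bias by it stays open. Variation between libraries that the groups do not explain cannot be told apart from a fracture effect: the exact permutation p was 0.01, which misses the threshold when adjusted over the 41 lists it was found among (0.137), so the bound of 0.05 written for the unadjusted p was too lenient. The adjusted p is hard to pass in turn, since the permutation p cannot fall below 0.005. The 7 week difference of 0.15 ± 0.124 fell to 0.000251 ± 0.0691 without male 7 weeks replicate 2, so 1 library may account for it. Without that library the 3 week difference was 0.20 ± 0.0651, and without female 3 weeks replicate 3 it was 0.16 ± 0.129.

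Blood cell genes were higher in Trap than in Input for all 8 genes, with a median of 2.40 (1.09 to 2.57) and a list score difference of 1.79 ± 0.217. Every gene of the neuron, microglia, endothelial and oligodendrocyte lists was lower in Trap, with medians of -4.02, -3.85, -2.82 and -2.41. This cannot decide about unspecific binding, since an astrocyte pull-down lowers other cell types whatever the background. Binding that takes up all tissue RNA alike would have the composition of Input and raise no gene above it. In 8 of 8 pairs of replicate 1 libraries the list was higher in Trap (0.763 to 2.48, exact sign test p 0.00781). That met the bound written beforehand for excluding blood content that differed between animals by chance. The pairs may not be independent, since all are replicate 1 and libraries of equal number deviated together within a sex. The differences were 1.51 to 2.48 in females and 0.763 to 1.23 in males. The test therefore does not exclude that explanation. Recombination in blood-forming cells and other routes were not tested, and no biological explanation was tested. The most abundant of these genes in the 32 libraries, Hbb-bs and Hba-a2, were higher by 2.42 ± 0.311 and 2.33 ± 0.295.

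A search for libraries far from the other 5 of their injury state found 4 among 80 sets of 6 values. Chance would give 4 if the sets were independent, but Mat2a and its copy have identical values. The count also does not weigh how far a library lies from the others. The mean log2 CPM of ribosomal protein genes was 6.74 in female 3 weeks replicate 3 (others 6.44 to 6.55) and 7.23 in male 7 weeks replicate 2 (others 6.24 to 6.38). Log2 CPM of Svil was 3.37 in female 5 weeks replicate 3 (others 4.25 to 4.60), and that of Rassf10 1.21 in female uninjured replicate 1 (others 1.66 to 1.86).

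Camera called lists for a sex difference in the fracture effect, given here as the median log2 difference, males minus females. Such calls are weak evidence. For each time against uninjured, other splits of the libraries gave medians of 13, 9 and 10 camera lists at 3, 5 and 7 weeks. Splits were not run for the lists of the sex difference. At 3 weeks it was -0.15 for oxidative phosphorylation (estimated-correlation p 0.418), -0.30 for cholesterol (p 0.0129), -0.17 for ribosomal protein (p 0.403) and 0.30 for glucocorticoid genes (p 0.0744). At 5 weeks it was -0.22 for oxidative phosphorylation (p 0.266), -0.12 for ribosomal protein (p 0.588) and 0.38 for glucocorticoid genes (p 0.0446). At 7 weeks it was 0.17 for neuron markers (p 0.424), 0.20 for oxidative phosphorylation (p 0.406), -0.11 for cholesterol (p 0.248) and 0.26 for ribosomal protein genes (p 0.340). The estimated correlation and fry called 0 of these lists. Several depend on 1 library, by the sex difference in mean log2 CPM. Without male 7 weeks replicate 2 it went at 7 weeks from 0.14 to -0.11 for oxidative phosphorylation and from 0.19 to -0.12 for ribosomal protein genes, and without female 7 weeks replicate 2 from 0.25 to -0.03 for neuron markers. Without female 5 weeks replicate 3 it went at 5 weeks from -0.19 to -0.06 for oxidative phosphorylation and from -0.10 to 0.01 for ribosomal protein genes. Without female 3 weeks replicate 3 it went at 3 weeks from -0.14 to -0.07 and from -0.17 to -0.07 for these lists, and without female uninjured replicate 1 from 0.39 to 0.23 for glucocorticoid genes. For cholesterol genes it went from -0.22 to -0.14 at 3 weeks without female 3 weeks replicate 1, and from -0.09 to -0.04 at 7 weeks without female uninjured replicate 1.

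Between 3 and 7 weeks edgeR found Nnat lower by -0.47 and Rflnb higher by 0.57. Camera called 12 lists between these times, for which splits were not run. The estimated correlation and fry called 0, each with 2 at p under 0.05 unadjusted. By their medians these were 0.081 for neuron (estimated-correlation p 0.457), 0.22 for oligodendrocyte (p 0.348) and 0.21 for Schwann cell markers (p 0.0388), 0.076 for oxidative phosphorylation (p 0.562), 0.079 for glycolysis (p 0.153), 0.092 for the tricarboxylic acid cycle (p 0.105), 0.12 for glycogen (p 0.118) and 0.056 for fatty acid oxidation genes (p 0.273). The others were glutamate genes at 0.050 (p 0.224), pan-reactive genes at -0.25 (p 0.154), glucocorticoid genes at 0.26 (p 0.0275) and autophagy genes at 0.063 (p 0.133). Without male 7 weeks replicate 2 the difference in mean log2 CPM went from 0.06 to -0.07 for oxidative phosphorylation, 0.06 to 0.03 for glycolysis, 0.08 to 0.05 for the tricarboxylic acid cycle and 0.05 to 0.02 for autophagy genes. Without female 3 weeks replicate 2 it went from 0.19 to 0.02 for neuron and from 0.24 to 0.08 for oligodendrocyte markers, and without female 7 weeks replicate 1 from 0.34 to 0.18 for Schwann cell markers. Without female 3 weeks replicate 3 it went from 0.10 to 0.06 for glycogen, 0.05 to 0.02 for fatty acid oxidation and 0.07 to 0.03 for glutamate genes.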

How the results depend on the processing

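The fits without both libraries that stood apart (female 3 weeks replicate 3, male 7 weeks replicate 2), with the block within sex and with permuted list scores, and the list scores without each library within and between the sexes and for 7 against 3 weeks, were chosen after the data were seen.

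The female to male Pearson correlation changed sign at 5 and 7 weeks over genes with mean log2 CPM above 3, while Spearman kept its sign, as given below. The count for Trap against Input stayed within 1.5 times under each alternative tried, and 2277 of 2279 values of its named genes kept their side of the threshold. DESeq2's size factors changed the count of calls by over 1.5 times in no comparison.

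For Trap at 3 weeks (17 calls) the count was 34 without the filter, 50 with the carry-over index, 47 among Trap-enriched genes, 135 by DESeq2 and 106 without both libraries (65 higher, 41 lower, all 17 shared). For females at 3 weeks (6) these counts were 25, 18, 21, 69 and 44, and for 7 against 3 weeks (3) 9, 11, 6, 57 and 51; with the groups compared only both were 0. The 106 included Stat3 (0.48 ± 0.0664, chosen after it was seen), and not Gfap. DESeq2 called 1 at 5 weeks, in males at each time and for each sex difference, and 11 for uninjured sexes. The groups compared only gave 4 in males at 3 weeks and 2 at 5 weeks. All 32 libraries in 1 fit gave 7, 0 and 0 for Input at 3, 5 and 7 weeks. The cause was not tested.

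With the replicate number as a block the counts were 44 at 3 weeks, 20 in females at 3 weeks, 11 for 7 against 3 weeks, and 1 in females at 5 weeks and at 7 weeks; with the block within sex they were 80, 60, 45, 1 and 1. Libraries of equal number deviated together within a sex (mean r 0.230 over 36 pairs, -0.167 to 0.652) and not across sexes (-0.00996), and 21 of 24 correlated best with their own number within the sex, against 8 by chance. This is a hint from the data, not from the design: per the file headers, column names carry a prefix by sex and number, which female replicate 1 lacks and whose meaning is not given. An earlier check on other genes, made when block counts had been seen, also left pairs under 0.1. Xist and Eif2s3x were not called with the block within sex. The block changed no other count by over 1.5 times.

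For Trap against Input 8 fits that each left out 1 library gave 13868 to 13966 calls, so not every library was left out there. Leaving out each library gave 3 to 47 calls at 3 weeks, 0 to 0 at 5 and 7 weeks, 1 to 27 in females at 3 weeks, 0 to 1 in females at 7 weeks, 5 to 6 for uninjured sexes and 0 to 38 for 7 against 3 weeks. At 3 weeks it was 4 without female uninjured replicate 1, 35 without female uninjured replicate 3, 8 without female 3 weeks replicate 2, 8 without male uninjured replicate 1, 4 without male 3 weeks replicate 1 and 11 without male 3 weeks replicate 2.

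Lists called at 3, 5 and 7 weeks (13, 15 and 2) were 0 with the estimated correlation, fry or permuted scores, and 6 to 17, 7 to 17 and 2 to 7 as each library was left out. Permuted scores could hardly call a list, since their p cannot fall below 0.005. At 7 weeks 1 was called with the carry-over index and 4 without both libraries, 0 shared. Trap against Input had 0 with the estimated correlation. The female to male Pearson r was 0.317, -0.126 and -0.0125 at 3, 5 and 7 weeks over genes with mean log2 CPM above 3 (Spearman 0.279, -0.185 and 0.0893). Within and between the sexes and for 7 against 3 weeks, differences in mean log2 CPM of lists called by camera kept their sign as each library was left out, apart from these ranges: in females at 3 weeks -0.22 to 0.00997 for astrocyte markers and -0.038 to 0.43 for interferon genes, in females at 5 weeks -0.052 to 0.15 for oxidative phosphorylation and -0.019 to 0.17 for ribosomal protein genes, and in males at 7 weeks -0.14 to 0.27 and -0.061 to 0.43 for the same 2 lists. For the sex difference they were -0.18 to 0.0092 at 5 weeks for ribosomal protein genes, and at 7 weeks -0.026 to 0.52 for neuron markers, -0.11 to 0.31 for oxidative phosphorylation and -0.12 to 0.37 for ribosomal protein genes. For 7 against 3 weeks oxidative phosphorylation had -0.067 to 0.14. Among values of named genes 144 lost and 14 gained a call. Depth limits genes near 1 CPM, such as St14 and Retnlg.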

Other observations

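The split of the libraries was compared with other splits of the same sizes, tests that were written before the counts of the splits were seen.

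For genes, 1 of 100 splits, the real one, called as many as the 13992 of Trap against Input (next 8818), and 1 of 100 as many as the 17 at 3 weeks (next 3). Both met the bound written beforehand for excluding chance, which was not adjusted over the comparisons. A share of 1 of 100 is the smallest these splits can give, and they take no account of the replicate number. The count was 0 at 5 weeks (highest other 0), at 7 weeks (1) and for the sex differences at 3, 5 and 7 weeks (3, 0 and 4). Every split reaches 0 whatever the data, so 100 of 100 splits for each of these says nothing about chance. For 7 against 3 weeks 2 of 100 splits called the 3 genes or more, which met the bound written beforehand for excluding chance. The other of them called 42, more than the real split, so the count is not taken to exclude chance. That split points to a structure of the samples: it was the real split with male 7 weeks replicate 2, the library that stood apart, exchanged for male 3 weeks replicate 3. Leaving out that 7 week library gave 38, and leaving out female 3 weeks replicate 1 gave 0. With 3 libraries against 3 the 10 splits are too few: the real and highest other counts were 6 and 2 in females at 3 weeks (1 of 10 splits), 0 and 1 in females at 5 weeks (10 of 10), 0 and 0 in females at 7 weeks and in males at 3, 5 and 7 weeks (10 of 10 each), and 6 and 0 for uninjured sexes (1 of 10).

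For camera lists, 3 of 100 splits called as many as the 28 of Trap against Input (highest other 28). That met the bound written beforehand for excluding chance. Other splits called a median of 21 lists and also reached 28, so the count is not taken to exclude chance. At 3 weeks 52 of 100 splits called at least the 13 lists (highest other 24), at 5 weeks 16 called at least 15 (highest other 23), and at 7 weeks all 100 called at least 2 (highest other 16), so chance was not excluded for the number of lists at any time after fracture.

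Fold changes of the 3 times share the uninjured libraries, and their correlations across genes were 0.501 (3 and 5 weeks), 0.438 (3 and 7 weeks) and 0.526 (5 and 7 weeks). Simulated unchanged groups gave means of 0.462, 0.490 and 0.470. The covariances were 0.0245, 0.0212 and 0.0226 against simulated 0.0235, 0.0252 and 0.0242, differences of 0.00103, -0.00398 and -0.00160. With the controls divided between the comparisons the correlations were 0.0480, 0.000569 and 0.0226.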
